A study of Danio rerio with 11 samples.

How the data were processed

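Messenger RNA was measured in fully grown ovarian follicles of adult zebrafish (Danio rerio) kept to 180 days after fertilisation. Per the labels' protocols, follicles above 650 µm were enriched on a 600 µm filter and picked by hand, RNA was taken up in Trizol, and libraries were made with the TruSeq RNA kit from RNA bound to poly-T beads. A follicle of this stage holds the oocyte together with its wall of granulosa and theca cells, and the bulk libraries carry RNA of all of them. The 11 libraries fall into 3 groups. The 3 control libraries came from fish heterozygous at fshb, lhb, fshr and lhcgr. The lhb/lhcgr mutant group has 4 libraries from fish that lack both functional copies of lhb and lhcgr and are heterozygous at fshb and fshr. The fshb/lhcgr mutant group has 4 libraries from fish that lack fshb and lhcgr and are heterozygous at lhb and fshr. Groups and replicate numbers were taken from the sample labels, which do not say outright that each replicate is a different fish, so the p-values measure only the spread between these samples. The kind of allele at each locus is not stated in the labels.

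The authors deposited a table of raw counts per gene, which holds 35889 genes. Of these, 31901 have Ensembl zebrafish identifiers and 3988 are models without one. Counts were used as deposited. They sum to between 14179252 and 25484718 per library. The authors also deposited FPKM values, in which each gene is divided by 1 fixed length. Deposited log2 fold changes and unadjusted p-values of both mutants against the controls come from the authors' tables, and the submitters' processing notes name DESeq2 1.20.0. The aligner, the counting tool, the use of strand and the genome build are not given in the sources used here, so no coordinates are printed. Reads of near-identical gene copies, such as the alpi and c3a families, and of overlapping or antisense genes could be split or shared in ways that these files do not show.

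Differences between groups were tested on the counts with edgeR 4.0.16 in R 4.3.3. The filter filterByExpr with its minimum count of 10 and minimum total of 15 kept 19421 genes. TMM factors scaled the libraries, and 1 quasi-likelihood model with a mean for each of the 3 groups and all 11 libraries was fitted robustly. The common biological coefficient of variation was 0.384. A gene was called when its p, adjusted by the Benjamini-Hochberg method over all genes tested, was under 0.05. Adjusted p-values of genes below are from this edgeR test unless another tool is named. Expression is given in CPM (counts of a gene per 1e6 counts of the library) scaled with the TMM factors, as mean ± SD over libraries. Log2 fold changes carry their standard error (SE), and a positive value is higher in the group named first. All tests were 2-sided. Where a group had 0 counts, the floor for a lower bound was 3 counts over the group, and intervals and floors cover counting error only.

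Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01. The p-values were adjusted over 84 tests, which are 28 lists in 3 comparisons. The lists covered steroidogenesis, gonadotropin and steroid receptors, the cAMP pathway, oocyte maturation, ovulation, growth factors, granulosa, theca, stroma and extracellular matrix, endothelium, macrophages and neutrophils, lymphocytes, erythrocytes, liver-made yolk proteins, oocyte genes, early meiosis, yolk proteolysis and hydration, cholesterol synthesis, immediate early and heat shock genes, apoptosis and p53, proliferation, complement and inflammation, cell junctions, Wnt, Notch and Hippo signalling, the male pathway, oxidative phosphorylation, ribosomal proteins and the mitochondrial genome. They were written from textbook knowledge of the ovary. For each list called by camera in a comparison, the number of called members is given over all genes tested and adjusted over the list alone.

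The groups, the tests, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule takes, in each comparison, the 6 called genes with the largest rise and the 6 with the largest fall among those with a mean of at least 5 CPM in the higher group, values that do not overlap between the groups and a symbol that is not a clone or locus placeholder. It adds called members of the lists with the smallest p, up to 3 from steroidogenesis, ovulation, oocyte maturation and growth factors and up to 2 from each other list. Finally it takes 10 genes in every comparison, called or not: lhcgr, fshr, lhb, fshb, cyp19a1a, cyp17a1, star, hsd20b2, pgr and igf3. Any other gene named was chosen after its values were seen.

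The alternatives fixed in advance were other scaling factors (RLE, upper quartile and library size only), no filter and a stricter filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, only the groups compared, the replicate number as a block, each library left out in turn, a 2-fold minimum, and limma-trend on log2 FPKM with pseudocounts of 1 and 0.1. Fold changes on the log2(FPKM + 1) scale understate those of low genes. For lists they were an estimated correlation, the rotation test fry, the block and each library left out. Those added after seeing the data were a correction of each library for gene length (a loess fit of span 0.5, with relative lengths from the ratio of counts to FPKM), leaving out lhb/lhcgr mutant 3 and 4 together, summing these libraries into 1, and thinning the deepest library at random. The trend with gene length was measured as a slope over 8798 genes above 16 CPM.

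The methods were tested on simulated data, after a first run on the deposited counts, with counts drawn from the means, spread and depth of these libraries, in which 100 genes changed by 1 and another 100 by 2 on the log2 scale. A further set of list genes was raised by 1, and its calls count in the totals but not as false. All changed genes were drawn above a minimum expected count, so the recovery does not cover low genes. Each comparison had 1 simulated data set with its own draw of changed genes. For lhb/lhcgr mutants against controls edgeR recovered 16% and 71% of them over 18885 genes, with 4 false calls among 100. For fshb/lhcgr mutants against controls it recovered 26% and 78% over 18889 genes, with 3 false calls among 116. Between the mutants it recovered 31% and 73% over 18887 genes, with 5 false calls among 122. DESeq2 made 33 false calls among 171, 30 among 175 and 30 among 183 in these simulations.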

Results

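Transcripts of fully grown follicles were compared between 3 control libraries, 4 lhb/lhcgr mutant libraries and 4 fshb/lhcgr mutant libraries. Totals ran from 14179252 counts in fshb/lhcgr mutant 3 to 25484718 in lhb/lhcgr mutant 3, and the other 9 libraries held between 15233928 and 15805763. Pairs of libraries correlated across genes (log2 CPM) at r of 0.923 to 0.944 in the controls, 0.927 to 0.949 in the fshb/lhcgr mutants and 0.929 to 0.979 in the lhb/lhcgr mutants, against 0.896 to 0.947 between groups. The closest pair was lhb/lhcgr mutant 3 and 4, whose counts still differed by 21.2 times the variance of sampling alone. The first 2 principal components held 24.3% and 14.4% of the variance. Gene values below carry the SD with n = 3 controls and n = 4 libraries of each mutant, and adjusted p-values are those of edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

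The mutated lhcgr (ENSDARG00000026081), which encodes the luteinising hormone receptor, kept its mRNA in every library. Its counts were 2282, 4735 and 1645 in the controls, 1899, 2010, 5051 and 2792 in the lhb/lhcgr mutants and 2180, 2458, 2214 and 1645 in the fshb/lhcgr mutants. The means of 197 ± 122, 148 ± 35.2 and 146 ± 30.7 CPM did not differ detectably (adjusted p = 0.494 for lhb/lhcgr mutants and 0.648 for fshb/lhcgr mutants against controls). The lhb gene (ENSDARG00000099363), which encodes the beta subunit of the hormone, had 294, 537 and 452 counts in the controls. It had 20, 160, 10 and 18 counts in the lhb/lhcgr mutants and 47, 25, 97 and 61 in the fshb/lhcgr mutants. The controls and the fshb/lhcgr mutants are both heterozygous for it. The log2 differences from the controls were -3.22 (SE 0.90, adjusted p = 0.0539) and -2.84 (SE 0.89, adjusted p = 0.293), neither past the threshold. Without lhb/lhcgr mutant 2, the library with 160 counts, both passed it, at -5.05 (adjusted p = 0.00114) and -2.84 (adjusted p = 0.0483).

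Counts of fshb (ENSDARG00000010841) were 0, 2 and 1 in the controls, 5, 5, 11 and 1 in the lhb/lhcgr mutants and 5, 0, 0 and 4 in the fshb/lhcgr mutants, too few for a test. The gene of the shared alpha subunit, cga (ENSDARG00000040479), had 0 counts in all 11 libraries. Both are pituitary genes. The 20-beta-hydroxysteroid dehydrogenase gene hsd20b2 also stayed below the expression filter.

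Between lhb/lhcgr mutants and controls, steroidogenesis genes had 1 higher, 2 lower and 23 not called (1 and 4 adjusted over the list alone), with a camera adjusted p of 0.847 (adjusted p = 0.937 with an estimated correlation). Ovulation genes had 3 higher, 3 lower and 42 not called (10 and 5 adjusted over the list alone), with 0.305 (adjusted p = 0.897 with an estimated correlation). Neither list shifted detectably in 1 direction. Fry's mixed test counts changes in either direction and does not compare a list with other genes. It gave an adjusted p of 1.86e-05 for each of these lists, and the same for the receptor and the Wnt, Notch and Hippo lists. Such values thus do not set steroidogenesis and ovulation genes apart. The estrogenic 17-beta-hydroxysteroid dehydrogenase gene hsd17b1 (ENSDARG00000027469) rose from 14.6 ± 7.20 to 51.1 ± 5.56 CPM (log2 difference 1.80, SE 0.35, adjusted p = 0.0123). The prostaglandin synthase gene ptgs2b (ENSDARG00000010276), whose products act in follicle rupture, rose from 15.9 ± 4.42 to 43.0 ± 7.18 CPM (1.43, SE 0.26, adjusted p = 0.00947). The membrane progestin receptor gene paqr7a (ENSDARG00000100462), whose protein takes part in oocyte maturation, fell from 7.26 ± 0.142 to 0.699 ± 0.451 CPM (-3.34, SE 0.60, adjusted p = 0.00878). The phosphodiesterase gene pde4ba (ENSDARG00000032868), whose enzyme breaks down cAMP, fell from 528 ± 97.2 to 203 ± 84.9 CPM (-1.37, SE 0.28, adjusted p = 0.0152). In each of these genes all 4 mutant libraries lay beyond all 3 controls, and each call held without any 1 library.

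The receptor gene fshr (ENSDARG00000071494), which granulosa cells use to sense follicle-stimulating hormone, rose from 12.4 ± 8.98 to 46.4 ± 5.29 CPM (1.91, SE 0.43, adjusted p = 0.0220). Its counts were 81, 317 and 145 in the controls, 689, 729, 1452 and 755 in these mutants and 223, 485, 257 and 215 in the fshb/lhcgr mutants. The fshr call was lost without control 1 (adjusted p = 0.0635), control 3 (0.0525) or lhb/lhcgr mutant 4 (0.0576). The nuclear progestin receptor gene pgr (ENSDARG00000035966), which is needed for ovulation, fell from 273 ± 108 to 117 ± 33.2 CPM (-1.23, SE 0.27, adjusted p = 0.0183), and its call was lost without lhb/lhcgr mutant 4 (0.0551). The cholesterol transport gene star (ENSDARG00000006137) fell from 25.6 ± 9.01 to 8.03 ± 2.91 CPM (-1.67, SE 0.41, adjusted p = 0.0309). That call was lost without control 1 (adjusted p = 0.125), control 3 (0.0555) or lhb/lhcgr mutant 1 (0.0739), 3 (0.0718) or 4 (0.0918). No difference was called for cyp17a1 (0.13, adjusted p = 0.692), the aromatase gene cyp19a1a (-1.81, adjusted p = 0.240) or igf3 (-0.33, adjusted p = 0.439).

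Among the largest falls, the bile acid synthesis gene cyp7a1 (ENSDARG00000069018) went down to 0.614 ± 0.491 CPM (-5.65, SE 0.58, adjusted p = 0.000260). The metalloproteinase gene mmp28 (ENSDARG00000059029) fell by 5.69 on the log2 scale (SE 0.68, adjusted p = 0.00119), and mgll (ENSDARG00000036820), whose enzyme splits monoglycerides, by 4.05 (SE 0.47, adjusted p = 0.000835). The alkaline phosphatase gene alpi.2 (ENSDARG00000053774) had 2 counts in the mutants against 801 in the controls, a ratio of 682 after scaling (95% counting interval 188 to 5640). For ccdc15 (ENSDARG00000067517) 0 counts stood against 279, at least 159-fold lower, with a call that was lost without control 1 (adjusted p = 0.0839) or lhb/lhcgr mutant 4 (0.0576). The cytokine gene tnfsf12 (ENSDARG00000069376) rose from 0.905 ± 0.618 to 16.7 ± 4.32 CPM (4.21, SE 0.66, adjusted p = 0.00518). The gene igfbp5b (ENSDARG00000025348), whose protein binds insulin-like growth factors, rose 12.4-fold to 214 ± 102 CPM (3.63, SE 0.61, adjusted p = 0.0104), a call that was lost without control 1 (0.0607).

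Of 19421 genes tested, 562 were higher and 864 lower in lhb/lhcgr mutants than in controls, among 4829 at an unadjusted p under 0.05. With libraries scaled by size only, which moved the median log2 difference of all genes from 0.01 to 0.12, 848 were higher and 578 lower. The counts fell to 90 and 207 without lhb/lhcgr mutant 4, 119 and 304 without control 1, 284 and 456 without lhb/lhcgr mutant 1, and 289 and 498 without lhb/lhcgr mutant 3. Of the 54 called genes that the naming rule selected, 20 kept their call without any 1 library, and 11 without both lhb/lhcgr mutant 3 and 4, an alternative chosen after seeing the data that leaves 2 libraries.

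**Figure D1:**
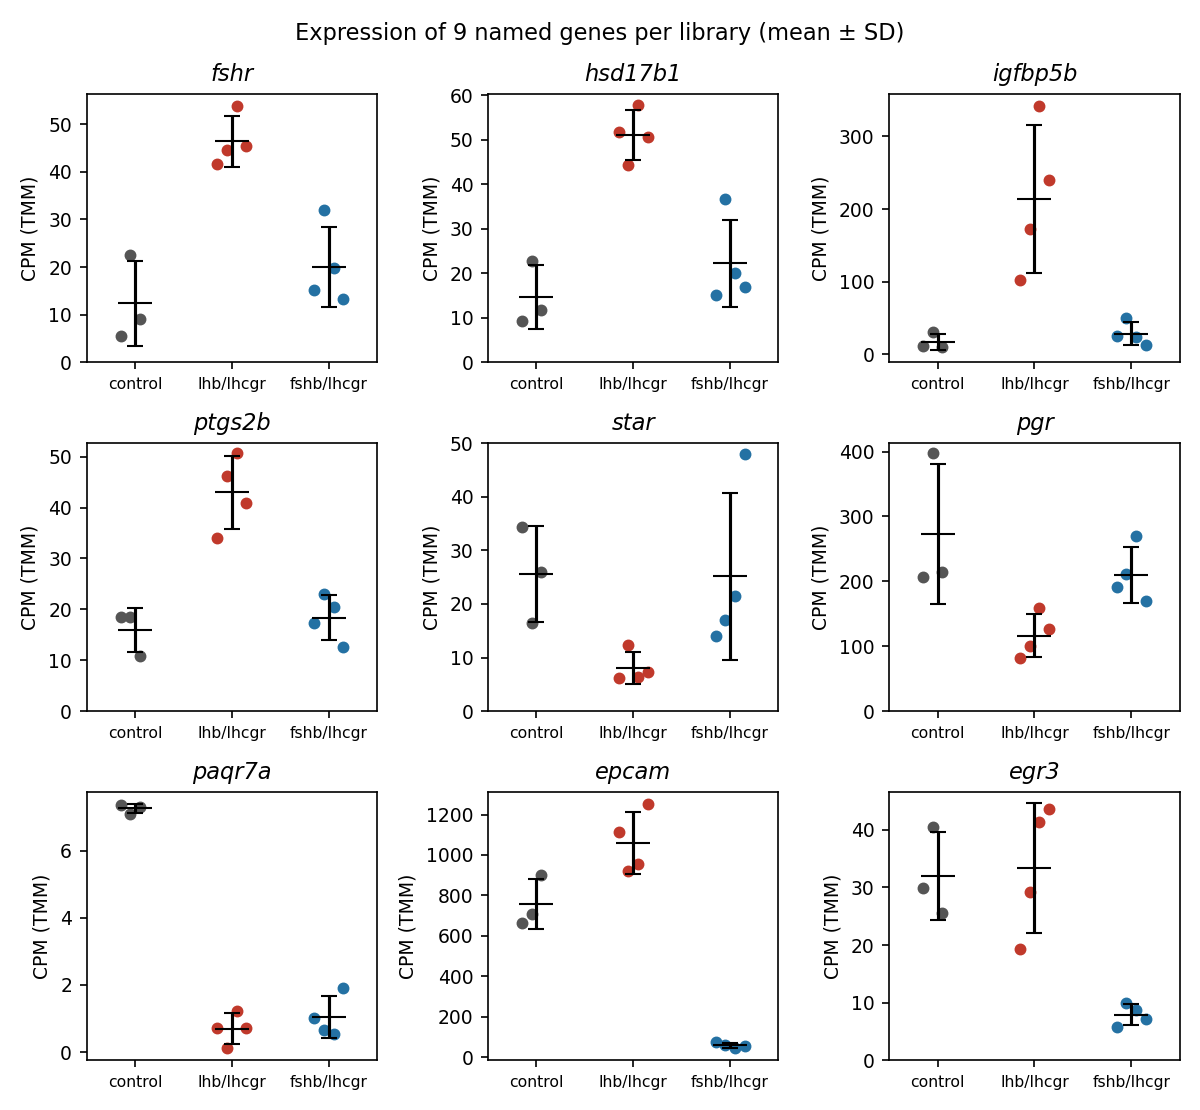
CPM of 9 genes in each library (points) with the mean and SD of the controls (n = 3), lhb/lhcgr mutants (n = 4) and fshb/lhcgr mutants (n = 4). The gene epcam averaged 60.0 CPM in fshb/lhcgr mutants against 757 in controls and 1061 in lhb/lhcgr mutants.

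Lists of ribosomal and mitochondrial genes differed in this comparison. Of 80 ribosomal protein genes, 24 were higher, 0 lower and 56 not called (58 higher and 1 lower adjusted over the list alone), with a median log2 difference of 0.57 and a camera adjusted p of 1.58e-17 (adjusted p = 0.695 with an estimated correlation). Oxidative phosphorylation genes of the nucleus had 6 higher, 2 lower and 80 not called (17 and 2 adjusted over the list alone), with a median of 0.28 and camera adjusted p = 2.73e-05 (adjusted p = 0.695 with an estimated correlation). The 13 protein genes of the mitochondrial genome had 6 lower and 7 not called (7 lower adjusted over the list alone), with a median of -0.73 and camera adjusted p = 0.000237 (adjusted p = 0.830 with an estimated correlation). Among them mt-atp8 (ENSDARG00000063910) fell by 1.66 on the log2 scale (SE 0.28, adjusted p = 0.00697). These 3 list calls held without any 1 library.

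Endothelial genes had 2 lower and 16 not called (3 lower adjusted over the list alone), with a median of -0.60 and camera adjusted p = 0.0108 (adjusted p = 0.830 with an estimated correlation), lost without control 2 (0.150). They include the vascular growth factor receptor genes kdrl (-1.51, SE 0.24, adjusted p = 0.00518) and flt1 (-1.79, SE 0.35, adjusted p = 0.0126). Stroma and matrix genes had 1 higher, 5 lower and 28 not called (1 and 11 adjusted over the list alone), with a median of -0.50 and camera adjusted p = 0.0108 (adjusted p = 0.830 with an estimated correlation). That call was lost without control 2 (0.0775) or control 3 (0.0521). In this list col12a1a fell (-1.30, SE 0.22, adjusted p = 0.00737) while its paralog col12a1b rose (1.70, SE 0.27, adjusted p = 0.00544). No macrophage and neutrophil gene of 27 was called by edgeR, also when adjusted over the list alone, while their median was 0.74 and camera's adjusted p 0.00721 (adjusted p = 0.830 with an estimated correlation). The camera call was lost without control 1 (0.194), lhb/lhcgr mutant 3 (0.0561) or lhb/lhcgr mutant 4 (0.0572). Cell junction genes had 2 lower and 32 not called (4 lower adjusted over the list alone), with a median of -0.19 and camera adjusted p = 0.0465 (adjusted p = 0.695 with an estimated correlation). It was lost without control 1 (0.0577), 2 (0.0508) or 3 (0.0777), lhb/lhcgr mutant 1 (0.0586), 2 (0.146) or 3 (0.0561), or fshb/lhcgr mutant 1 (0.0520).

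Log2 differences also followed relative gene length. In the shortest of 5 classes of genes their median was 0.27 in lhb/lhcgr mutants and 0.15 in fshb/lhcgr mutants against controls, and in the longest it was -0.25 and -0.19. Spearman's rho across genes, which are not independent replicates, was -0.238, -0.193 and, between the mutants, 0.118. Among the more highly expressed genes, from which the slopes come, it was -0.473, -0.428 and 0.252. The slope per doubling of length was 0.217, 0.142 and 0.0674 in the controls, -0.170, -0.116, -0.0115 and -0.0993 in the lhb/lhcgr mutants, and between -0.0197 and 0.00215 in the fshb/lhcgr mutants. After a correction for length, camera's adjusted p for lhb/lhcgr mutants against controls was 2.99e-12 for ribosomal proteins, 3.66e-07 for the mitochondrial genome, 0.0283 for endothelial genes and 0.0148 for macrophages and neutrophils. The calls of 3 lists ended. The median of oxidative phosphorylation genes shrank from 0.28 (quartiles 0.06 to 0.51) to 0.10 (-0.08 to 0.31), with an adjusted p of 0.277, and that of stroma and matrix genes from -0.50 (-0.87 to -0.04) to -0.28 (-0.63 to 0.08), with 0.305. The median of cell junction genes did not shrink, at -0.19 (-0.65 to -0.06) before and -0.26 (-0.52 to -0.03) after, with 0.0745.

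**Figure D2:**
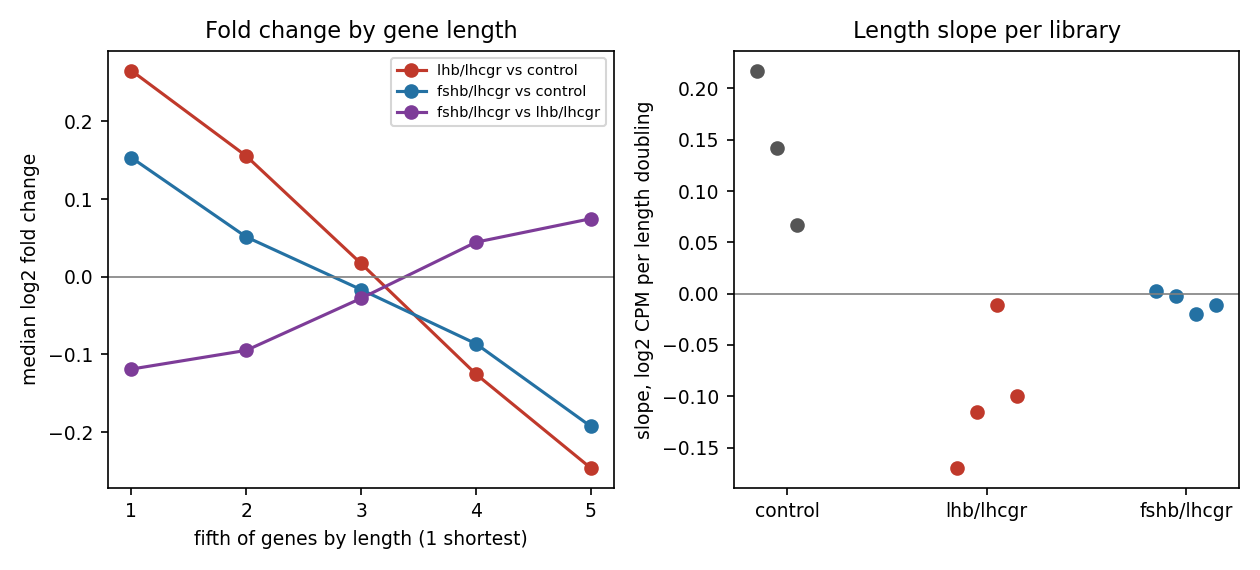
Median log2 difference of genes in 5 classes of relative length for the 3 comparisons, and the slope of log2 CPM on length in each library. The medians of lhb/lhcgr mutants against controls run from 0.27 in the shortest class to -0.25 in the longest.

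Between fshb/lhcgr mutants and controls, epcam (ENSDARG00000040534), which encodes an epithelial adhesion protein, fell from 757 ± 125 to 60.0 ± 12.2 CPM (-3.66, SE 0.20, adjusted p = 7.99e-07). All 4 mutant libraries lay below all controls, and the call held without any 1 library. The bile acid gene cyp7a1 fell here too, to 2.06 ± 1.14 CPM (-3.88, SE 0.53, adjusted p = 0.0200). That call was lost without control 1 (adjusted p = 0.0622) or fshb/lhcgr mutant 1 (0.0616), 2 (0.0734) or 4 (0.0735). The immediate early transcription factor gene egr3 (ENSDARG00000089156) fell from 32.0 ± 7.67 to 7.86 ± 1.82 CPM (-2.02, SE 0.29, adjusted p = 0.0200). It was lost without control 1 (adjusted p = 0.0622) or 2 (0.0661) or fshb/lhcgr mutant 1 (0.0791), 2 (0.0734), 3 (0.0575) or 4 (0.0735).

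In all, 3 genes were higher and 11 lower, among 2291 at an unadjusted p under 0.05, and DESeq2 called 124 higher and 154 lower. The 3 and 11 became 0 and 1 without control 1 and also without fshb/lhcgr mutant 2. The lower genes numbered 6 without control 2, 3 without fshb/lhcgr mutant 1, 4 without fshb/lhcgr mutant 3 and also without 4, and 18 without lhb/lhcgr mutant 1. The higher genes numbered 5 without control 3, 7 without lhb/lhcgr mutant 2, and 1 without lhb/lhcgr mutant 3 and also without 4. Of the 7 called genes that the naming rule selected, 1 kept its call without any 1 library and 5 without both lhb/lhcgr mutant 3 and 4. No difference was called for fshr (0.70, adjusted p = 0.532), star (-0.03, adjusted p = 0.987), pgr (-0.38, adjusted p = 0.613), cyp17a1 (0.08, adjusted p = 0.897), cyp19a1a (0.21, adjusted p = 0.955) or igf3 (-0.15, adjusted p = 0.853).

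Immediate early and heat shock genes, which respond within minutes to growth factors and stress, were lower as a list. In lhb/lhcgr mutants against controls the list was not called (median -0.12, camera adjusted p = 0.559). It passed there as lower without both lhb/lhcgr mutant 3 and 4 (0.0427). In fshb/lhcgr mutants 2 of 41 were lower and 39 not called (19 lower adjusted over the list alone), with a median of -0.79 and camera adjusted p = 1.86e-10 (adjusted p = 0.695 with an estimated correlation). The 10 heat shock members had a median of -0.02 (5 negative), and the 31 others of -1.07 (29 negative). Oocyte genes had 0 of 40 called, also over the list alone, with a median of 0.36 and camera adjusted p = 1.23e-07 (adjusted p = 0.695 with an estimated correlation). Stroma and matrix genes had 0 of 34 called, also over the list alone, with a median of 0.56 and camera adjusted p = 2.43e-06 (adjusted p = 0.695 with an estimated correlation). Erythrocyte genes had 0 of 14 called, also over the list alone, with a median of 0.83 and camera adjusted p = 0.000235 (adjusted p = 0.695 with an estimated correlation). These 4 list calls held without any 1 library.

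The other list calls of this comparison each hung on a library. Ribosomal proteins (median 0.20, camera adjusted p = 1.78e-07, and adjusted p = 0.830 with an estimated correlation) were lost without control 1 (0.140). So were oxidative phosphorylation genes (0.19, adjusted p = 0.000237, and adjusted p = 0.745 with an estimated correlation), at 0.0582 without control 1, and macrophage and neutrophil genes (0.32, adjusted p = 0.00532, and adjusted p = 0.830 with an estimated correlation), at 0.482. Cholesterol synthesis genes (-0.27, adjusted p = 0.0180, and adjusted p = 0.695 with an estimated correlation) were lost without control 1 (0.170). Genes of the cAMP pathway (-0.34, adjusted p = 0.0138, and adjusted p = 0.695 with an estimated correlation) were lost without control 2 (0.159) or fshb/lhcgr mutant 4 (0.0559), and oocyte maturation genes (0.18, adjusted p = 0.0180, and adjusted p = 0.745 with an estimated correlation) without the same libraries (0.149 and 0.105) or with the replicate number as a block (0.0573). In these 6 lists no member was called over all genes, and adjusted over the list alone 3 cholesterol genes were lower, 1 cAMP gene higher and 3 lower. After the length correction the median of oxidative phosphorylation genes went from 0.19 (quartiles -0.01 to 0.34) to 0.06 (-0.11 to 0.21), with an adjusted p of 0.327. That of cAMP genes stayed about as large, from -0.34 (-0.68 to 0.16) to -0.33 (-0.54 to 0.14), with 0.0503, just past the threshold.

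Lists called in another comparison also passed in places where they were not called with all libraries. For fshb/lhcgr mutants against controls the mitochondrial genome had 0 of 13 called, also over the list alone, with a median of 0.29 and camera adjusted p = 0.147 (adjusted p = 0.897 with an estimated correlation). It passed without control 2 (0.00143) or fshb/lhcgr mutant 4 (0.000995), or with the replicate number as a block (0.0200). Endothelial genes had 0 of 18 called there, also over the list alone (median -0.14, adjusted p = 0.564, and adjusted p = 0.910 with an estimated correlation), and passed without control 1 (0.0326). For lhb/lhcgr mutants against controls, cAMP genes (adjusted p = 0.112) passed without lhb/lhcgr mutant 3 (0.0354), erythrocyte genes (0.271) without lhb/lhcgr mutant 1 (0.0317), and oocyte genes (0.354) without control 3 (0.0488) or lhb/lhcgr mutant 3 (0.0354). Between the mutants, erythrocyte genes (0.112) passed without lhb/lhcgr mutant 3 (0.0326), and oxidative phosphorylation genes (0.112) without lhb/lhcgr mutant 3 (0.0326) or fshb/lhcgr mutant 3 (0.0485).

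**Figure D3:**
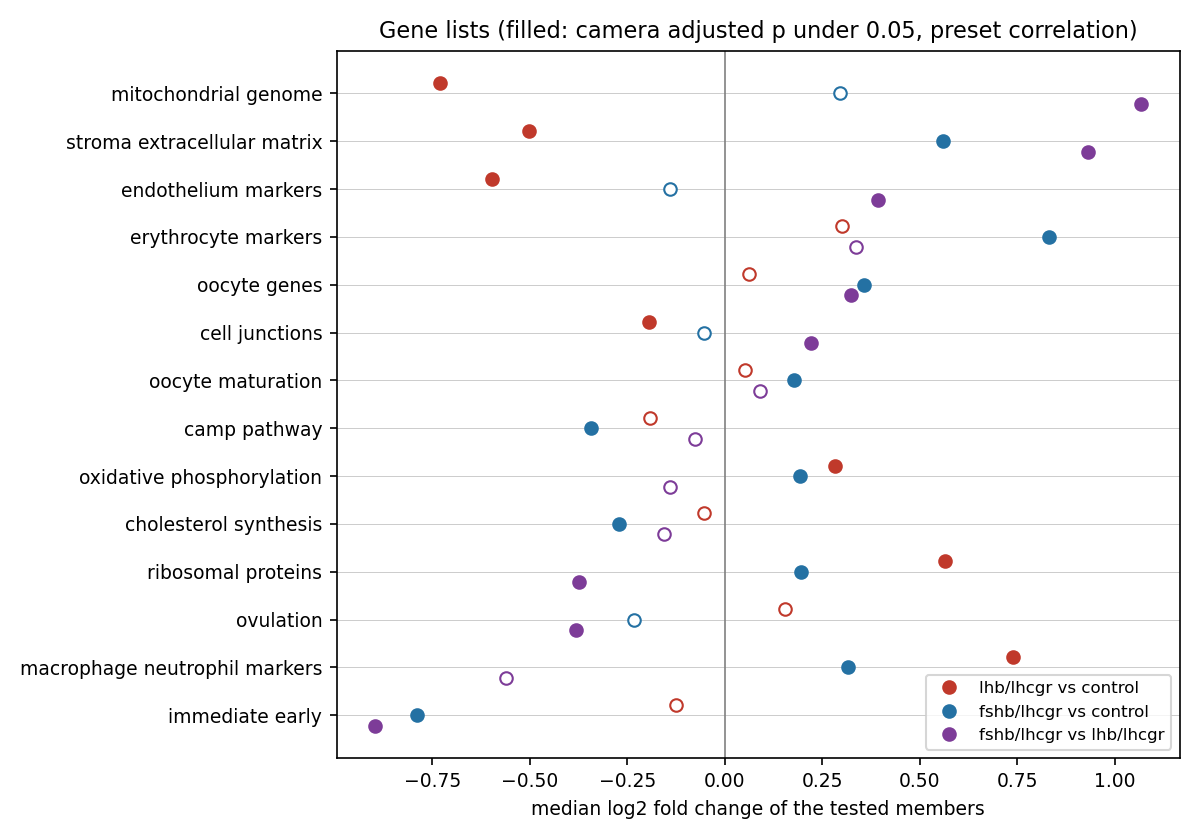
Median log2 difference of the tested members of 14 gene lists in the 3 comparisons, with filled points where camera's adjusted p with a preset correlation was under 0.05. Stroma and matrix genes have a median of -0.50 in lhb/lhcgr mutants and 0.56 in fshb/lhcgr mutants against controls.

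Between fshb/lhcgr mutants and lhb/lhcgr mutants, epcam was lower by the largest margin relative to its error (-4.14, SE 0.20, adjusted p = 1.34e-07). The immediate early genes egr3 (-2.09, SE 0.28, adjusted p = 0.00313) and egr2a (ENSDARG00000044098; -3.27, SE 0.52, adjusted p = 0.00792) were lower in fshb/lhcgr mutants. So was the prostaglandin transporter gene slco2a1 (ENSDARG00000061896), 10.9-fold below the 12.1 ± 4.56 CPM of lhb/lhcgr mutants (-3.45, SE 0.43, adjusted p = 0.00193). The collagen genes col1a2 (ENSDARG00000020007; 1.76, SE 0.21, adjusted p = 0.00163) and col1a1a (ENSDARG00000012405; 1.64, SE 0.22, adjusted p = 0.00313), which make the fibres of connective tissue, were higher. The potassium channel gene kcnh6a (ENSDARG00000001803) had 45.3 ± 12.5 against 4.85 ± 1.04 CPM (3.23, SE 0.29, adjusted p = 0.000134). The nucleoside phosphorylase gene pnp5a (ENSDARG00000078619) had 1336 ± 542 against 140 ± 52.1 CPM (3.26, SE 0.36, adjusted p = 0.00122). The mitochondrial gene mt-atp6 was higher as well (1.53, SE 0.23, adjusted p = 0.00550). These 9 calls held without any 1 library.

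The endothelial receptor gene kdrl was higher in fshb/lhcgr mutants (1.30, SE 0.23, adjusted p = 0.0104), a call lost without lhb/lhcgr mutant 4 (0.0522). The prostaglandin synthase gene ptgs2b was lower (-1.23, SE 0.24, adjusted p = 0.0182), which was lost without lhb/lhcgr mutant 3 (0.0666) or 4 (0.0599) or fshb/lhcgr mutant 1 (0.0634). The cholesterol transport gene star was higher (1.65, SE 0.39, adjusted p = 0.0458), at 25.1 ± 15.5 against 8.03 ± 2.91 CPM. That call was lost without control 3 (0.0569), lhb/lhcgr mutant 1 (0.0935), 3 (0.134) or 4 (0.140), or fshb/lhcgr mutant 2 (0.0501), 3 (0.0878) or 4 (0.0958). No difference was called for fshr (-1.21, adjusted p = 0.112), which passed without control 1 (0.0465) or control 2 (0.0261), nor for pgr (0.85, adjusted p = 0.0917), which passed without control 2 (0.0369). Aromatase cyp19a1a (2.02, adjusted p = 0.238), lhcgr (-0.02, adjusted p = 0.982), lhb (0.38, adjusted p = 0.863), cyp17a1 (-0.06, adjusted p = 0.900) and igf3 (0.18, adjusted p = 0.737) were not called either.

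In total 282 genes were higher and 178 lower in fshb/lhcgr mutants than in lhb/lhcgr mutants, among 3502 at an unadjusted p under 0.05. With scaling by library size only, 200 were higher and 318 lower, with a median shift of -0.15 against -0.02. The counts became 75 and 29 without lhb/lhcgr mutant 4, 94 and 35 without lhb/lhcgr mutant 3, 118 and 41 without fshb/lhcgr mutant 1, and 107 and 55 without fshb/lhcgr mutant 3. They became 504 and 291 without control 1, and the lower genes alone 96 without fshb/lhcgr mutant 4 and 279 without control 2. Of the 39 called genes that the naming rule selected, 19 kept their call without any 1 library and 5 without both lhb/lhcgr mutant 3 and 4.

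Stroma and matrix genes were higher in fshb/lhcgr mutants than in lhb/lhcgr mutants, with 12 of 34 higher, 0 lower and 22 not called (21 and 2 adjusted over the list alone), a median of 0.93 and camera adjusted p = 2.88e-11 (adjusted p = 0.695 with an estimated correlation). The mitochondrial genome had 6 of 13 higher and 7 not called (9 higher adjusted over the list alone), with a median of 1.07 and camera adjusted p = 1.44e-08 (adjusted p = 0.695 with an estimated correlation). Immediate early and heat shock genes had 9 of 41 lower and 32 not called (1 higher and 19 lower adjusted over the list alone), with a median of -0.90 and camera adjusted p = 2.51e-07 (adjusted p = 0.745 with an estimated correlation). Ribosomal proteins had 0 of 80 called, also over the list alone, with a median of -0.37 and camera adjusted p = 2.62e-09 (adjusted p = 0.830 with an estimated correlation). These 4 calls held without any 1 library. Oocyte genes (1 higher, 39 not called, 8 higher adjusted over the list alone, median 0.32, camera adjusted p = 0.00206, and adjusted p = 0.830 with an estimated correlation) were lost without lhb/lhcgr mutant 3 (0.0937). Endothelial genes (2 higher, 16 not called, 2 higher adjusted over the list alone, median 0.39, adjusted p = 0.0138, and adjusted p = 0.830 with an estimated correlation) were lost without fshb/lhcgr mutant 3 (0.199).

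Cell junction genes (1 higher, 33 not called, 2 higher and 1 lower adjusted over the list alone, median 0.22, camera adjusted p = 0.0338, and adjusted p = 0.695 with an estimated correlation) were lost without lhb/lhcgr mutant 2 (0.113) or fshb/lhcgr mutant 3 (0.0565) or 4 (0.0559), and had 0.0503 after the length correction, with a median about as large (quartiles 0.03 to 0.36 before, and 0.20 with 0.01 to 0.42 after). Ovulation genes (1 higher, 3 lower, 44 not called, 4 higher and 8 lower adjusted over the list alone, median -0.38, adjusted p = 0.0385, and adjusted p = 0.830 with an estimated correlation) were lost without control 1 (0.0529), lhb/lhcgr mutant 2 (0.0531), 3 (0.198) or 4 (0.0587), or fshb/lhcgr mutant 1 (0.09996) or 4 (0.0836). No list call in any comparison held with an estimated correlation, where the smallest adjusted p was 0.695, and fry's directional test gave at least 0.0616.

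The other lists were not called by camera in any comparison. For lhb/lhcgr mutants against controls, fshb/lhcgr mutants against controls and between the mutants, the adjusted p was 0.847, 0.867 and 0.967 for steroidogenesis, 0.555, 0.447 and 0.967 for gonadotropin and steroid receptors, and 0.477, 0.383 and 0.897 for growth factors. It was 0.304, 0.469 and 0.511 for granulosa, 0.968, 0.198 and 0.284 for theca, and 0.847, 0.395 and 0.597 for lymphocytes. For liver-made yolk proteins it was 0.198, 0.224 and 0.759, for early meiosis 0.692, 0.190 and 0.447, and for yolk proteolysis and hydration 0.878, 0.597 and 0.564. For the male pathway it was 0.967, 0.555 and 0.694. Members of these lists were called all the same. In lhb/lhcgr mutants against controls, 1 receptor gene was higher and 2 lower, and 1 growth factor gene was higher and 2 lower. Also called there were 2 granulosa and 2 yolk proteolysis genes, higher, and 1 theca and 2 male pathway genes, lower. Between the mutants 1 steroidogenesis, 1 theca and 1 male pathway gene were higher, and 2 growth factor and 2 yolk proteolysis genes lower. Granulosa genes passed without control 2 against both mutants (0.0285 and 0.0156), as did theca genes for fshb/lhcgr mutants (0.0185). Median, mean and test differed in sign for steroidogenesis, receptors, growth factors and Wnt, Notch and Hippo genes between the mutants, for theca genes in lhb/lhcgr mutants, and for complement and p53 genes in fshb/lhcgr mutants.

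**Figure D4:**
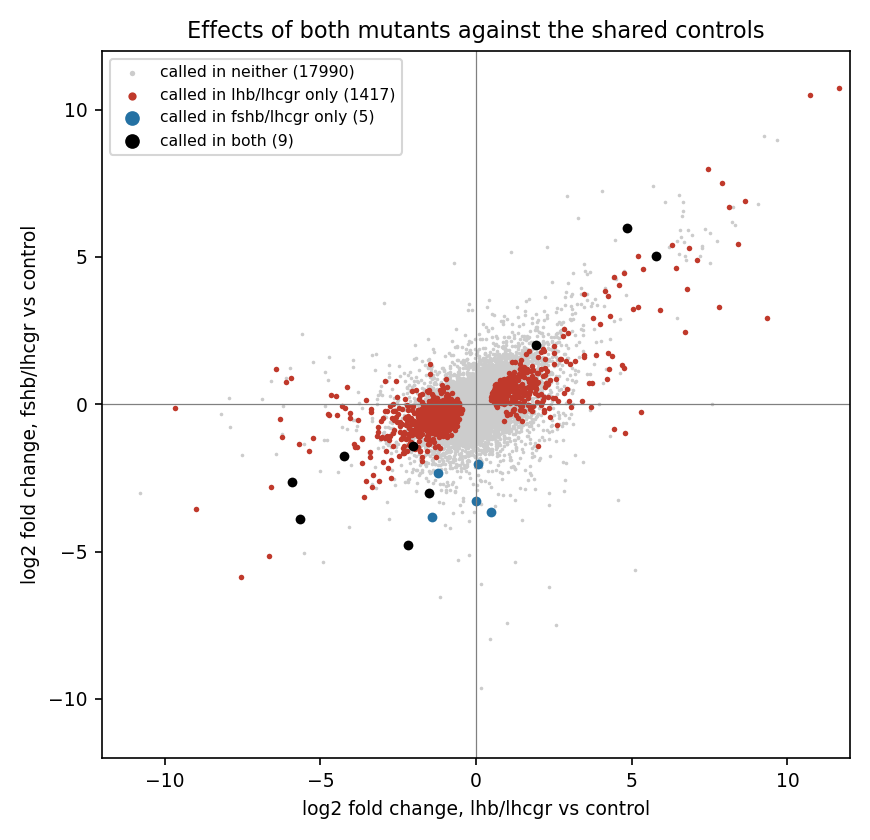
Log2 difference from controls of each tested gene in lhb/lhcgr mutants (x axis) and fshb/lhcgr mutants (y axis). Of the genes, 1417 were called in lhb/lhcgr mutants only, 5 in fshb/lhcgr mutants only, 9 in both and 17990 in neither.

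Both mutants shared 9 called genes, 3 higher and 6 lower, and 0 in opposite directions. Independent lists of these sizes would share 0.0868 higher and 0.489 lower, a figure that leaves the shared controls out of account. The 9 count became 0 without control 1 and also without fshb/lhcgr mutant 2, 5 without control 2 and also without lhb/lhcgr mutant 3 or 4, 4 without fshb/lhcgr mutant 1, and 2 without fshb/lhcgr mutant 4. Across genes, log2 differences correlated at r = 0.553, and their covariance was 0.405. In 20 simulations of unchanged mutants these were 0.587 (SD 0.0116) and 0.208 (SD 0.00709). All 11 libraries were redrawn there gene by gene, with 3 drawn controls shared by both comparisons. Shifts of whole libraries, such as the trend with gene length, were thus left out. The larger covariance therefore cannot tell an effect shared by both mutants from such shifts in the shared controls. Both comparisons use the same 3 controls, which cannot be split into separate sets of at least 2. Over all genes 71.0% had the same sign in both mutants, against 69.3% in the simulations. In the authors' deposited tables, all 1426 and 14 called genes had the same sign as here, and log2 fold changes correlated across genes at r = 0.990 and 0.991 with the authors' deposited tables. Those tables describe the same samples, so the match checks the processing and is no independent evidence.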

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

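The tests of explanations and the other splits of the libraries in this part were chosen only after the result was seen. For the summing of lhb/lhcgr mutant 3 and 4, chosen then too, the bound was written before its outcome was known. The search for libraries far from the rest of their group was part of the work from the start.

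Among 167 groups of 4 libraries, 7 had 1 library far from the other 3, where chance alone gives about 5%, or 1 in 20 groups. All 7 lay in the lhb/lhcgr mutants. In lhb/lhcgr mutant 1, abcc6a stood at 0.966 CPM against 13.7 to 21.2 in the others, flt1 at 7.003 against 5.13 to 5.39, mgll at 0.423 against 2.45 to 3.06, and cox6b1 at 2.60 against 5.84 to 6.79. In lhb/lhcgr mutant 4, alpi.2 stood at 0.120 CPM against 0, and in lhb/lhcgr mutant 3 pla2g1b stood at 0.186 CPM against 0, both near the limit of detection. The total of lhb/lhcgr mutant 3 was 25484718 counts against 15525728 to 15776603.

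Many more genes were called in lhb/lhcgr mutants (1426) than in fshb/lhcgr mutants (14) against the same controls. The ratio was smaller at an unadjusted p under 0.05, with 4829 against 2291 genes, where chance alone gives about 971. DESeq2 called 1197 higher and 1530 lower genes against 124 and 154. The 14 calls thus do not show that fshb/lhcgr mutants were nearly unchanged. The tables argue against 3 technical causes as the whole of the gap, though not as a part. The bound was loose, since a cause would have counted as the whole only if nearly all calls were lost. With the deepest library thinned to 15539933 counts, 1388 of the 1426 genes kept their call and direction. After the correction for gene length 732 did, and 506 with lhb/lhcgr mutant 3 and 4 summed into 1 library. The length correction left 307 higher and 498 lower genes, against 3 and 14 in fshb/lhcgr mutants. The summing left 171 and 335, against 1 and 9. Without both of these libraries, which leaves 2 of that group, 18 genes were higher and 111 lower, so much of the count rests on the pair or on the number of libraries, and these 3 causes were not tried in combination. Between the mutants themselves 460 genes were called, 276 of them among the 1426, so the gap in counts does not show that the other genes differed between the mutants. The loss of lhb in place of fshb may contribute, as a hypothesis that the design names and no test here isolates.

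Of the 35 ways to split the libraries of each comparison into groups of these sizes, 1, the real one, called as many genes in each of the 3 comparisons. The real split called 1426, 14 and 460 genes, and the highest of the other splits 82, 8 and 3, for lhb/lhcgr mutants against controls, fshb/lhcgr mutants against controls, and between the mutants. A share of 1 in 35 is the smallest that these splits can give. It argues against chance only if the libraries are independent samples, which the labels do not state outright. For fshb/lhcgr mutants against controls the ranking rests on few genes: the 14 became 1 without control 1 and also without fshb/lhcgr mutant 2, and at an unadjusted p under 0.05 the real split gave 2291 genes against 2216 in the highest of the others.

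Immediate early genes were lower as a list in fshb/lhcgr mutants than in controls by camera with a preset correlation, though 2 of 41 were called and the adjusted p was 0.695 with an estimated correlation and 0.153 with fry. A trend with gene length is argued against as the whole cause, since the correction moved the median from -0.79 to -0.86. Camera's adjusted p with the preset correlation was then 1.78e-11. A smaller share of stroma cells would lower stroma genes too. Their median log2 difference of 0.56 (quartiles 0.23 to 0.74) argues against it as the whole cause, though 0 of 34 were called. For granulosa and theca cells of the follicle wall the question stays open, since their genes went both ways. Medians were 0.03 (quartiles -0.21 to 0.24) for granulosa and 0.15 (-0.01 to 0.34) for theca genes. Tissue handling before lysis cannot be told apart from an effect of the genotype, because the 10 heat shock members, which handling could also move, went both ways (median -0.0212, quartiles -0.99 to 0.30, 5 negative), while 29 of the 31 other members were negative (median -1.07). An effect of the lost fshb on signalling in the follicle stays open and untested.

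Stroma, endothelial and macrophage lists passed camera with a preset correlation in lhb/lhcgr mutants against controls, and none of them with an estimated correlation (adjusted p = 0.830 for each). For stroma genes a trend with gene length cannot be told apart from a change in the tissue: after the correction the median went from -0.50 (quartiles -0.87 to -0.04) to -0.28 (-0.63 to 0.08). The call ended (adjusted p = 0.305), while more than 0.5 of the shift was left. A smaller share of wall cells also stays open, since granulosa genes, which it would lower as well, went both ways (median 0.56, quartiles -0.39 to 1.02). For endothelial genes the correction moved the median from -0.60 (quartiles -0.87 to -0.29) to -0.39 (-0.90 to -0.13). Camera's adjusted p with the preset correlation was then 0.0283. That argues against length as the whole cause only under the preset correlation, since no estimated one was tried after the correction. The macrophage and neutrophil list had an adjusted p of 0.836 without lhb/lhcgr mutant 3 and 4, as needed if these libraries carried it, but the call was also lost without control 1 (0.194) or without either of the pair (0.0561 and 0.0572).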

How the results depend on the processing

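The correction for gene length, the summing or joint removal of lhb/lhcgr mutant 3 and 4 and the thinning of the deepest library were chosen after seeing the data, and the other alternatives were not. Direction was compared only where a result was called under either setting. Counts below are of higher and lower genes for lhb/lhcgr mutants against controls, fshb/lhcgr mutants against controls, and between the mutants, where they moved by more than 1.5 times. In all of these the cause was not tested, except where fewer libraries, fewer genes tested or the added 2-fold minimum shows it.

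With library size only, 848 genes were higher in the first comparison, 17 lower in the second and 318 lower in the last. DESeq2, which made more false calls on simulated data, gave 1197 and 1530, 124 and 154, and 775 and 626, with 165 shared by both mutants. With no filter the second gave 5 and 19, with 14 shared. Limma-voom gave 0 and 6 in the second, with 4 shared. Using only the groups compared gave 284 and 495 in the first, 6 higher in the second, and 570 and 321 in the last. The replicate number as a block gave 324 higher in the first and 6 lower in the second. Deviations from the group means correlated weakly for equal numbers. The values were 0.116, -0.0129 and 0.0436 in the first comparison, 0.0987, 0.0808 and -0.0844 in the second, and 0.122, 0.0322, 0.115 and -0.0179 in the last. The closest library of the other group bore the same number for replicate 1 in the first, 1 and 2 in the second, and 1, 2 and 3 in the last. A pairing by number is thus neither shown nor excluded.

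On log2(FPKM + 1) the second comparison gave 6 and 19, and on log2(FPKM + 0.1) it gave 6 higher. Unfiltered log2(FPKM + 1) gave 348 lower in the first and 101 and 85 in the last. On log2(FPKM + 1), 48.8% of the calls in the first were lower, against 60.6%. A 2-fold minimum left 229 and 519 in the first. The length correction gave 307 and 498 in the first. Without lhb/lhcgr mutant 3 and 4 there were 18 and 111 in the first and 23 and 4 in the last. Summed, they gave 171 and 335 in the first, 1 higher in the second and 84 and 33 in the last, with 4 shared.

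Leaving out each library in turn gave 90 to 526 higher and 207 to 922 lower genes in the first comparison, 0 to 7 and 1 to 18 in the second, 75 to 504 and 29 to 291 in the last, and 0 to 11 shared. Of 167 counts under the alternatives fixed in advance, 96 stayed within 1.5 times. Of 2760 values of named genes, 2348 kept their side of the threshold, 394 lost their call, 18 gained one and 0 reversed. Of 1176 list results, 1072 kept their side, 83 lost and 21 gained a call. Under the added alternatives 345 of 480 gene values and 154 of 168 list results kept their side. There the macrophage and neutrophil list between the mutants, lower but not called with all libraries (adjusted p = 0.579), passed in the other direction without lhb/lhcgr mutant 3 and 4 (0.0304). Without them, camera also called cAMP (adjusted p = 0.00475), oocyte (0.0154) and immediate early genes (0.0427) in lhb/lhcgr mutants against controls. Erythrocyte genes passed between the mutants (0.00475).

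In simulations at the depth, number and spread of these libraries, edgeR found 16%, 26% and 31% of genes that differed by 1 on the log2 scale in the 3 comparisons. Those genes were drawn above a minimum expected count, and no other depth or number was tried.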

Other observations

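The tests of neighbouring genes in this part were chosen only after the result was seen, and the lists were not. Genes of Wnt, Notch and Hippo signalling, which steer growth and differentiation of follicle cells, included several changes in lhb/lhcgr mutants against controls. The Wnt scaffold gene axin1 fell (-1.46, SE 0.24, adjusted p = 0.00613) and amotl2b, whose protein restrains the Hippo effector YAP, rose from 30.9 ± 3.61 (n = 3) to 90.4 ± 22.7 CPM (n = 4; 1.55, SE 0.20, adjusted p = 0.00167), and both calls held without any 1 library. Of the 45 genes 1 was higher, 7 lower and 37 not called (3 and 7 adjusted over the list alone), and camera's adjusted p was 0.511. The other lower genes, chosen after their values were seen and not tried without single libraries, were axin2 (-0.89), yap1 (-0.56), jag2b (-1.34), lats1 (-0.73), lef1 (-1.30) and wnt11 (-1.99). Camera's adjusted p was 0.555 for fshb/lhcgr mutants against controls, with 0 called, and 0.759 between the mutants, with 1 higher and 2 lower. There amotl2b was lower in fshb/lhcgr mutants (-1.08, SE 0.18, adjusted p = 0.00958).

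In lhb/lhcgr mutants against controls, complement and inflammation genes had 3 higher, 2 lower and 30 not called (5 and 3 adjusted over the list alone, camera adjusted p = 0.539). Apoptosis and p53 genes had 3 higher and 34 not called (5 higher adjusted over the list alone, 0.109). Proliferation genes had 1 higher, 3 lower and 36 not called (3 and 5 adjusted over the list alone, 0.354), with 0.0285 without control 2. For fshb/lhcgr mutants against controls these 3 lists had adjusted p of 0.555, 0.847 and 0.555, and between the mutants 0.190, 0.0934 and 0.0627. Between the mutants complement genes passed without fshb/lhcgr mutant 2 (0.0359). Proliferation genes passed there without control 1 (0.0436) or 2 (0.0371), lhb/lhcgr mutant 1 (0.0192) or 2 (0.0167), or fshb/lhcgr mutant 3 (0.0185).

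The 3 genes higher in fshb/lhcgr mutants than in controls were fut9b (2.02, SE 0.33, adjusted p = 0.0444) and the unnamed loci si:dkey-93m18.4 (5.99) and si:ch211-194m7.5 (5.04). In controls these loci stood at 0.215 ± 0.198 and 0.0447 ± 0.0389 CPM, near the limit of detection. In fshb/lhcgr mutants they had 14.4 ± 6.74 and 1.70 ± 1.00 CPM. The size of their log2 differences is therefore uncertain. The fut9b call was lost without any 1 library other than lhb/lhcgr mutant 1 or 2, at adjusted p from 0.0718 (lhb/lhcgr mutant 4) to 0.147 (control 2). The loci were chosen after their values were seen and were not tried without single libraries. All 3 were also called higher in lhb/lhcgr mutants. Mitochondrial mRNA made up 8.45 ± 3.31% of counts in controls (n = 3), 6.63 ± 1.17% in lhb/lhcgr mutants (n = 4) and 9.53 ± 2.56% in fshb/lhcgr mutants (n = 4).

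Genes beside a mutated locus could differ through the chromosome segment inherited with the mutation. Among the 20 nearest tested genes, matched by symbol for 81.0% of Ensembl genes, 9 beside lhb and 6 beside lhcgr had an unadjusted p under 0.05 in lhb/lhcgr mutants against controls. In fshb/lhcgr mutants 5 did beside lhcgr and 4 beside fshb. The adjusted share of 10000 random windows with as many genes was 0.240, 0.432, 0.240 and 0.331, so no excess was shown, and none is excluded with 20 genes per window.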
